A study of Mus musculus with 2 samples.

How the data were processed

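Total RNA of kidney Tregs was labelled with Cy3 and hybridised to 2 single-colour Agilent mouse arrays, 1 for each lot of anti-GBM antibody. Per the file headers and the submitters' processing notes, spots were quantified with Agilent Feature Extraction 10.7.1.1. The main values are the processed signal intensity of each spot, which per the file headers was corrected for background and detrended within the array but not normalised between arrays. The deposited scanner output also gave the raw median intensity of each spot and of its local background, and other flags of 0 or 1 for saturation, outliers and detection per the file headers. The deposited value table held a linear ratio for each probe, with column medians of 0.070 and 0.069. How the authors made this ratio is not given in the sources used here. The comparison with the scanner output showed it to be the processed signal divided by 1 constant per array near its 75th percentile, not a log value and not centred by gene.

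Each column of the value table was set against both scanner outputs over probes with a signal of at least 300. The logarithm of signal over value had an SD of 0.000163 over 13642 probes for array 1 and 0.000160 over 13525 probes for array 2 against the column of the other lot. Against the column of the same lot it had an SD of 0.157 and 0.182. The 2 sources therefore assign the arrays to lots in opposite ways. Array 1 is the one recorded under lot I in the scanner output. The value table was used as an alternative source with its columns taken by their labels. Scale and centring were settled by this comparison, and direction was not.

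Signals were log2-transformed, and the 75th percentile of the array over non-control probes was subtracted. Of 62976 spots per array, 3671 were control spots and were left out. Outlier spots (75 on array 1 and 56 on array 2) were also left out, and no spot was saturated. Spots of one probe were averaged. Probes were named through a table of RefSeq accessions and symbols (assembly GRCm38.p6), used for names only because the array files name another build. Of 56605 probes, 35886 carried a RefSeq accession and 32994 (58.3%) received a single symbol, for 22911 genes, while 23611 had no symbol and stood outside the gene results. A gene's difference was the mean over its probes well above background on both arrays. Of 5125 genes with several such probes, 1997 had probes that differed in sign, among them 1 gene with a difference of 2-fold or more. Genes well above background on 1 array only were given a lower bound, the level on the bright array minus the higher of the dim array's detection floor (the lowest signal among its probes well above background) and the probe's own level there. Floors lay at -4.62 on array 1 and -4.58 on array 2.

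Header fields for protocol, scan date, grid, software and scanner were the same on both arrays, so no batch could be separated. The scanner's quality summary called array 1 in range and asked for an evaluation of array 2, whose spike-in detection limit was out of range. The slope of the spike-in curve was 0.938 and 0.910. The number of arrays limits the precision. With 1 array per lot, no test was run and no p-value is given, and genes were counted by size at 2-fold.

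Lists of genes for Treg programmes, helper T cell programmes, T cell states, metabolism and other cell types, 32 in all, were fixed before the data were examined, as were the alternatives, the counting rule and the rule for named genes. A list's median difference was compared with 10000 random lists of the same size drawn from 20 bins of mean level. Named genes were the 10 with the largest and the 10 with the smallest difference among genes with an assigned symbol, defined in the same way, whose probes were all well above background, without flags and of one sign. The rule further named the 3 largest lower bounds in each direction among genes with an assigned symbol (no clone, Gm or LOC number), 15 Treg and helper genes in every case, and up to 4 members per list with the largest differences, apart from members named for detection. Beyond this rule, Aqp1, Mki67, Hspa1a, Hspa1b, Cd4, Ifng, Il4, Il13, Kap, Umod and the genes named for families and for glucocorticoid response were named after their values were seen. A few genes that the rule names are not reported here.

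Alternatives were normexp background correction (offset 50), scaling by the median of genes or by spike-ins, no scaling, quantile normalisation, lowess centring (span 0.3), no filter and a stricter filter on dim probes (4 times the floor), outlier spots kept, the brightest probe per gene, the value table, other fold limits (1.5 and 4), another detection flag and list members at their bounds. The design named a mean signal for normexp, but the median signal column was used. Counts over 3 spot errors, above the 75th percentile and without genes of the nephron lists were chosen after seeing the data. So were further lists of proximal tubule genes and of glucocorticoid-induced genes. The nephron lists are those of proximal tubule, with its further list, and of distal nephron and collecting duct.

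The procedure was tested on simulated data built on the 13743 measured genes. Random differences were drawn independently from a normal distribution whose spread came from the median absolute deviation of genes of similar level. Of genes given a difference of 1.5 on the log2 scale, 98% were counted as 2-fold higher, and of those given -1.5, 96% as lower. Of 13543 unchanged genes, 27 (0.199%) were counted. Of 200 unchanged lists, 4% fell outside the central 95%, and all 50 lists of 16 genes shifted by 0.2 fell above it. The simulation holds no outlying spots and no joint variation of genes, so these shares are not error rates of the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.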

Results

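Regulatory T cells (Tregs) were sorted from mouse kidney on day 28 of cGN, an antibody-mediated kidney injury set off with antibodies against the glomerular basement membrane (anti-GBM). The sorted cells carried CD45, CD3e, CD4 and a FoxP3-hCD2 reporter, which shows human CD2 on cells that express Foxp3. RNA from these cells was hybridised to 2 single-colour arrays. One array was made for anti-GBM lot I and the other for lot M, and the labels state that the severity of disease depended on the lot. The titles number the arrays as repeats of one condition. They were therefore used both to describe which genes were detected in the RNA of these sorted cells and to compare the lots, with 1 array per lot. The comparison has no replicate check and no test, and every difference describes these 2 arrays. On array 1, 30576 of 56605 probes (54.0%) were well above background, and on array 2, 30558 (54.0%). Both arrays measured 13743 named genes, 296 genes were measured on array 1 only, 377 on array 2 only and 8490 on neither.

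The sources contradict each other on which array belongs to which lot. Array 1 is recorded under lot I and array 2 under lot M in the scanner output, whereas the deposited value table holds the values of array 1 under lot M and those of array 2 under lot I. The arrays are therefore named by number. All differences are array 2 minus array 1 on the log2 scale, which is lot M minus lot I by the scanner output and lot I minus lot M by the value table. The error given with a gene's difference comes from the scanner's error model for single spots and holds no variation between mice or lots.

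The genes that define Tregs were measured on both arrays at similar levels. Foxp3, the transcription factor of the Treg lineage, had a level of 4.92 on array 1 and 4.74 on array 2, as log2 of signal over the array's 75th percentile, a difference of -0.17 ± 0.20. Gata3, a transcription factor of type 2 immunity that is also used by Tregs in tissues and is named in the title of the study, had a level of 7.32 on array 1 and 7.34 on array 2 (difference 0.02 ± 0.20). Il1rl1, which encodes the receptor for interleukin 33, differed by 0.06 ± 0.12, and Areg, which encodes the tissue repair factor amphiregulin, by -0.16 ± 0.20. Il2ra, the high-affinity chain of the interleukin 2 receptor, differed by 0.12 ± 0.20, and the differences of Ctla4, Ikzf2, Ccr8 and Klrg1 lay between 0.02 and 0.07. All 18 genes of the Treg core list were well above background on both arrays, with a median difference of -0.03, and so were all 20 genes of the list for tissue Tregs and repair, with a median of 0.06. The median of the Treg core list became 0.01 when the brightest probe stood for each gene. Pdcd1, the inhibitory receptor PD-1, had a difference of 0.25 ± 0.20. Differences over 1 error in the other direction included -0.31 ± 0.20 for the cytokine Il10, -0.26 ± 0.14 for Rora and -0.28 ± 0.20 for the type 1 regulator Tbx21. The chemokine receptor gene Cxcr3 differed by -0.09 ± 0.20.

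**Figure D1:**
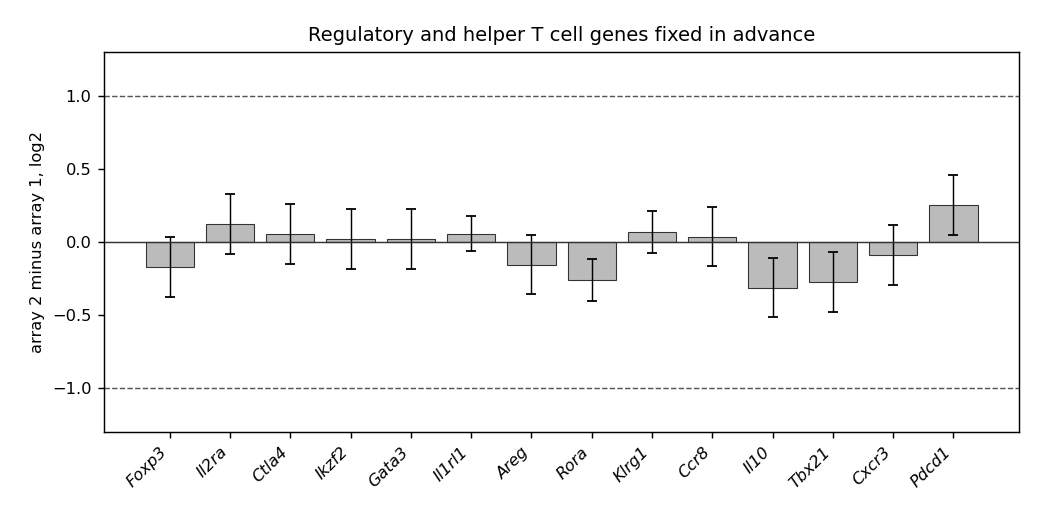
Bars give the log2 difference (array 2 minus array 1) of 14 regulatory and helper T cell genes chosen in advance, error bars the spot error of the scanner's error model, and dashed lines a 2-fold difference. Every bar lies between -0.31 and 0.25.

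Transcripts of the helper T cell programmes were also detected in the RNA of the sorted cells. Genes of kidney epithelium and of macrophages were detected there too, so which cells the helper transcripts came from was not determined. The type 1 list had 13 of 14 genes measured on both arrays, including Ifng, Cxcr3 and Tbx21. The type 2 list had 11 of 14, including the cytokine genes Il4, Il5 and Il13. The last 2, with 1 probe each, were dim: Il5 at -2.85 and -3.41 and Il13 at -3.91 and -3.82 on arrays 1 and 2. The detection floors were -4.62 and -4.58. With the stricter filter on dim probes 8 genes of this list remained. The type 17 list had 9 of 12, but its effector cytokines Il17a, Il17f and Il22 were not well above background on either array. The median difference was -0.09 for the type 1 list, with 6 of 13 members higher and 7 lower, and 9969 of 10000 random lists of the same size and expression level had a median at least as high. Within it Cxcr6, a homing receptor of tissue T cells, was lower in array 2 (-0.30), while Eomes was 2-fold higher (1.19) at a level below the 75th percentile on both arrays. The type 2 median of 0.06 and the type 17 median of -0.06 lay within the central 95% of random lists, and the type 17 median turned to 0.02 with no filter on dim probes. Follicular helper genes had a median of 0.13, with 11 of 12 higher in array 2, but 0.065 over its 6 members with a mean level above the 75th percentile. Cebpa (0.56), Tox2 (0.45) and Ascl2 (0.34) had its largest differences, at levels below the 75th percentile on both arrays.

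Between the arrays, 184 genes were 2-fold or more higher in array 2 and 12 were 2-fold or more higher in array 1, together 1.43% of the genes measured on both. Genes of kidney epithelium stood out among those higher in array 2. Of the 16 genes in the proximal tubule list, 15 were higher in array 2 and 8 by 2-fold or more, with a median of 1.01 (2.01-fold), above all 10000 random lists. They included Slc5a2, the tubular glucose transporter SGLT2 (1.59), Lrp2, the endocytic receptor megalin (1.20), Slc34a1, a phosphate transporter (1.20), and Slc27a2, a fatty acid transporter (1.18). Aqp1, a water channel, was the exception at -0.15. All 14 genes of the list for distal nephron and collecting duct were higher in array 2, with a median of 0.44 and the largest differences in Aqp2, the water channel of the collecting duct (1.60), and Pvalb, a calcium-binding protein of the distal convoluted tubule (1.41). Every gene of both lists was well above background on both arrays, although the sort was for T cells.

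**Figure D2:**
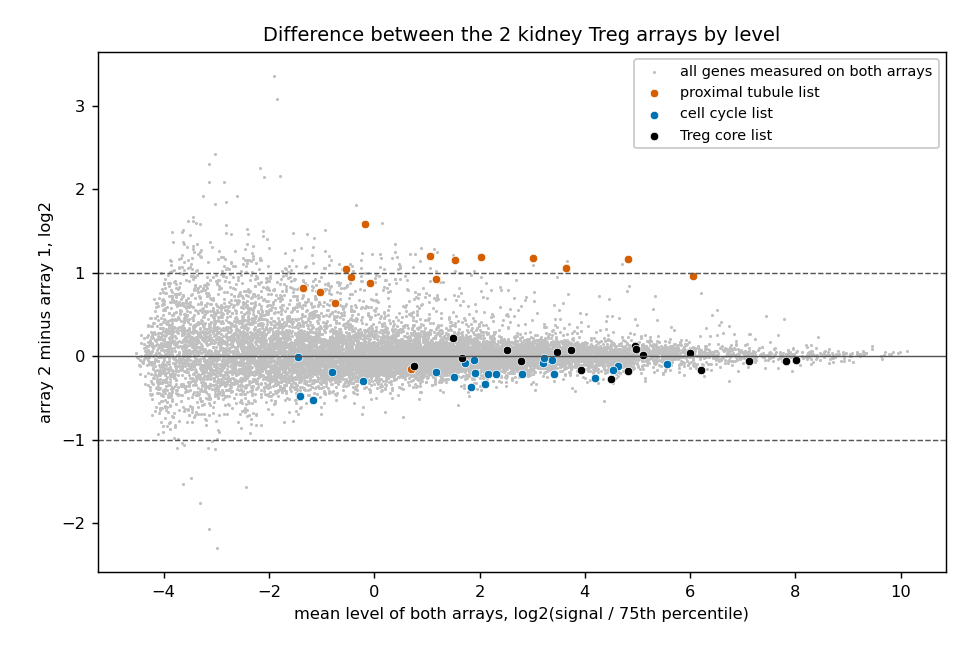
Each point is a gene measured on both arrays, placed by its mean level (x axis, log2 of signal over the 75th percentile) and its difference (y axis, array 2 minus array 1, log2), with dashed lines at 2-fold. Of the coloured lists, 15 of 16 proximal tubule genes lie above 0, all 24 cell cycle genes below 0, and the Treg core genes scatter around it with a median of -0.03.

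Markers of the other cells that the sort should exclude had lower medians than the proximal tubule list. Macrophage and monocyte genes had a median of 0.28, above all 10000 random lists, with 12 of 14 higher in array 2. These included Adgre1, which encodes F4/80 (0.46), the complement gene C1qc (0.42) and Apoe (0.41), while the chemokine receptor gene Ccr2 was lower (-0.41). Endothelial genes had a median of 0.03 and podocyte genes of 0.04, both within the central 95% of random lists. The podocyte median rests on 4 of 9 genes, and its random lists ran from -0.26 to 0.51, so it says little. Nphs1, which encodes nephrin of the podocyte slit diaphragm, was not well above background on either array. The median was 0.20 for CD8 T and natural killer cells, where the natural killer receptor gene Klra8 was 2-fold or more higher (1.92, from 1 of its 3 probes). It was 0.22 for fibroblasts and mesangial cells, -0.11 for B and plasma cells, and 0.05 for dendritic cells and MHC class II. For mast cells, basophils and eosinophils it was 0.06, over 3 of 10 genes. All these medians lay within the central 95% of random lists. Some left it under an alternative. These were B and plasma cells with no filter on dim probes (-0.26), fibroblasts and mesangial cells with the brightest probe (0.25), and CD8 T and natural killer cells with normexp (0.17). The 4 measured genes of red cells and platelets had a median of 0.51, with Pf4 at 0.54 and Hba-a1 at 0.52, which was 0.039 and within the central 95% with no filter on dim probes. The 7 measured neutrophil genes had a median of 0.28 that turned to -0.01 with no filter on dim probes and to -0.13 with a stricter one. T cell identity genes such as Cd3e (0.11) and Cd4 (-0.02) had a median of -0.02 over all 15 members.

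Genes of cell division were lower in array 2. All 24 genes of the cell cycle list had negative differences, with a median of -0.19, below all 10000 random lists. The largest were in the mitotic genes Bub1 (-0.52), Kif11 (-0.48) and Ube2c (-0.37) and in Top2a, the DNA topoisomerase of dividing cells (-0.33), and Mki67, which encodes Ki-67, differed by -0.25. Genes that interferon gamma induces were lower too, in 17 of 18 members, with a median of -0.18, below all 10000 random lists. They included the chemokine gene Cxcl9 (-0.69) and the GTPase genes Iigp1 (-0.41) and Gbp4 (-0.29). Type I interferon response genes had a median of -0.07 with 13 of 16 lower. Heat shock and unfolded protein genes had a median of 0.17, above all 10000 random lists, with 10 of 15 higher in array 2. The chaperone genes Hsph1 (0.70), Dnajb1 (0.38) and Hspd1 (0.37) were higher, whereas Hspa1a (-0.24) and Hspa1b (-0.18) were lower.

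Metabolic and homing genes differed by small amounts. Cholesterol and fatty acid synthesis genes had a median of -0.11, with 14 of 18 lower in array 2, including the desaturase gene Scd2 (-0.25) and Insig1, a regulator of sterol synthesis (-0.18). Oxidative phosphorylation genes and glycolysis and hypoxia genes each had a median of 0.07, and cytosolic ribosomal protein genes 0.03. Chemokine receptor and homing genes had a median of -0.05, suppressive effector molecules -0.06, co-inhibitory and co-stimulatory receptors 0.05, naive and central memory genes 0.08, and immediate early genes of T cell receptor signalling -0.003. Scaling by the spike-in controls would lower every difference by 0.06, so the sign of a smaller positive median depends on the scaling, and normexp background correction turned the signs of the immediate early and B cell lists. In all, 18 of the 32 lists lay outside the central 95% of random lists, 10 above and 8 below, where 1.6 would fall by chance if the genes of a list varied independently. Of these, 12 stayed outside on the same side under 6 alternatives (normexp, quantile normalisation, intensity-dependent centring, both other filters and the brightest probe). The Treg core, tissue Treg, follicular helper, glycolysis, neutrophil and red cell lists did not. Some lists inside the central 95% moved outside it under an alternative, such as naive and central memory genes (0.15 with the brightest probe). List members at their bounds, an alternative for 8 lists, were not part of this comparison. Genes of one pathway do not vary independently, and apart from the proximal tubule, distal nephron and red cell lists no list median exceeded 0.28 in size.

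**Figure D3:**
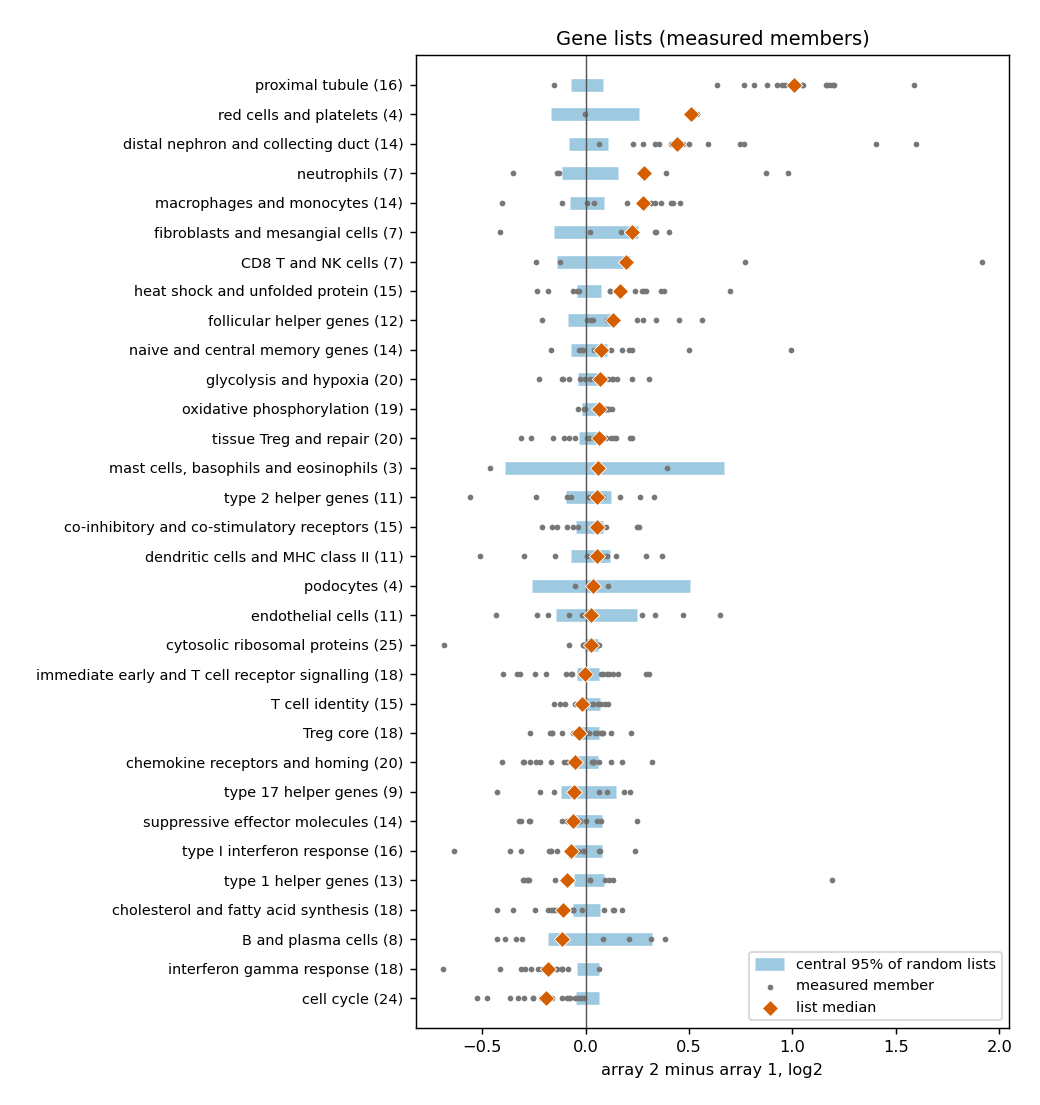
Grey points are the members of each of the 32 gene lists measured on both arrays (number in brackets), diamonds the list medians, and blue bars the central 95% of 10000 random lists matched for size and level, all as log2 differences (array 2 minus array 1). The proximal tubule list has the highest median, 1.01, and the cell cycle list the lowest, -0.19.

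Single genes with the largest differences were mostly weakly expressed. Among genes with an assigned symbol whose probes were all well above background, free of flags and of one sign, the largest differences higher in array 2 were those of Hrc, a calcium-binding protein of the sarcoplasmic reticulum (2.16 ± 0.23), the glycosyltransferase gene B3galnt1 (2.15 ± 0.24), the fibrinogen gene Fgb (2.09 ± 0.28) and the laminin gene Lama1 (1.93 ± 0.34). Gorasp1, Mlana, Pdk4, Tmem82, Steap1 and Elovl2 followed with differences from 1.60 to 1.84. Under the same conditions, higher in array 1 were the renin gene Ren2 (-2.30 ± 0.30), which is nearly identical to Ren1 and therefore uncertain as to its source, the cell cycle transcription factor E2f4 (-1.76 ± 0.34), Frs3 (-1.57 ± 0.24) and Syce1 (-1.11 ± 0.27). Tmem51os1, Hand2, Olfr1441, Kbtbd3, Kbtbd6 and Ankrd66 followed with differences from -1.06 to -0.91. Some larger differences lay outside these conditions, in genes with clone names and in genes with a further probe not well above background on both arrays. The latter included 3.36 for Reps2 and 3.08 for Itga9, and -2.07 for the urea transporter gene Slc14a2, all named after their values were seen. Each of these genes rests on 1 measured probe, and 149 of the 184 genes higher in array 2 and all 12 higher in array 1 had a mean level under the 75th percentile of the probes. Among genes with an assigned symbol well above background on 1 array only, the B cell chemokine gene Cxcl13 was at least 17.4-fold higher in array 2, the keratin gene Krt71 at least 16.5-fold and the vomeronasal receptor gene Vmn1r54 at least 14.2-fold. In array 1, Tex50 was at least 9.06-fold higher, the embryonic globin gene Hbb-y at least 8.43-fold and the transcription factor gene Foxn4 at least 7.24-fold. Of genes known by clone or model numbers, Gm10684 had a bound of 21.6-fold in array 1, above all of these, and 4930480E11Rik one of 14.7-fold in array 2. Bounds of 2-fold or more were reached by 74 such genes in array 2 and 41 in array 1.

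The arrays were otherwise close. Of the genes measured on both, 12923 (94.0%) lay within 1.5-fold, and Pearson's r across genes was 0.995, where genes are not independent replicates. The spread between arrays was 1.27 to 1.71 times the spread expected from repeated spots on one array, which leaves out labelling and hybridisation. The 8 spike-in controls measured on both arrays had a median difference of 0.06 (0.01 to 0.08) after scaling, as large as or larger in size than the medians of several lists, such as Treg core and T cell identity. Under background correction with normexp, 28 genes were 2-fold higher in array 2 and 0 in array 1.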

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

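Most tests here were chosen after the result was seen, namely those on endothelial, distal nephron and macrophage genes, on centring of the proximal tubule list, on T cell identity genes, on the value table and on the headers. The further proximal tubule list and the centring of the cell cycle list were fixed before their own values were seen.

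Proximal tubule genes had a median difference of 1.01 between arrays of sorted T cells, and a sort on CD45, CD3e, CD4 and the Foxp3 reporter should remove tubular cells. A lower share of T cells that raised every other cell type alike is argued against by the endothelial list, with a median of 0.026. That median lay 0.98 (95% interval 0.62 to 1.24) below the proximal tubule list. A signal-dependent bias shared by all genes is argued against by the random lists matched for level, all of which had lower medians. Intensity-dependent centring left a median of 1.02, but it was no separate test because the random lists were already matched for level. A candidate explanation is that more proximal tubule RNA was carried into array 2. A further list of proximal tubule genes had a median of 0.98, with all 30 measured members higher and 14 by 2-fold or more. That list extends the pattern to more genes. It cannot decide the cause, because any cause that raised proximal tubule genes together would raise it too. The abundant tubular transcript Kap was at 5.58 on array 1 and differed by 0.96, while Umod of the thick ascending limb, at 6.35 on array 1, differed by 0.42. Whether such carry-over followed from more tubular injury with one antibody lot was not tested, since each lot has 1 array.

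Cell cycle genes were lower in array 2 in all 24 members, with a median of -0.19. Dilution of T cell RNA by RNA of other cells is argued against by the T cell identity list, whose median was -0.015. A signal-dependent bias shared by all genes is argued against by the random lists matched for level, all of which had higher medians. Intensity-dependent centring left a median of -0.18, but it was no separate test because those lists were already matched for level. A difference between the lots in how many Tregs were dividing may remain as an explanation, and it is untested with 1 array per lot.

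The value table and the scanner output contradict each other on the lots. An interchange of the 2 arrays between these sources is a candidate explanation: against the column of its own label the smaller SD of log2 signal over value was 0.157, and against the other column it was 0.000163 for array 1 and 0.000160 for array 2. These SDs are the values from which the contradiction was seen, so they describe the interchange and are no separate test of it. Whether the scanner output or the value table is wrong cannot be told apart, because 0 header cells naming a sample held text in the files used here. No biological explanation applies to this pattern, and it leaves the sign of every difference between lots open.

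Probes without a gene symbol stood outside all comparisons by gene. Of 9309 such probes measured on both arrays, 53 were 2-fold or more higher in array 2 and 44 in array 1, a more even split than the 184 and 12 named genes.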

How the results depend on the processing

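Counts over 3 spot errors, above the 75th percentile and without the genes of the nephron lists were chosen after seeing the data. Leaving out the value table, 326 alternative medians were compared over all 32 lists. Changes of sign were counted only for the 18 lists outside the central 95% of random lists, and 3 of their medians changed sign. Lists inside it changed sign as well, such as cytosolic ribosomal genes (-0.031 with spike-in scaling) and endothelial genes (-0.0165 with quantile normalisation). Among 341 alternative values of named genes no 2-fold difference changed sign. The Treg core list was at 0.012 with the brightest probe, and the neutrophil list at -0.013 without a filter on dim probes and at -0.13 with a stricter one. The 184 genes higher in array 2 and 12 in array 1 became 28 and 0 with normexp, 648 and 399 without a filter. They were 708 and 112 at 1.5-fold, 9 and 2 at 4-fold, and 35 and 0 above the 75th percentile. Normexp adds an offset of 50, which shrinks differences of dim probes, but it also starts from the raw median signal. The effects of these changes were not tested apart. With the stricter filter the counts were 150 and 7. Without the 60 measured genes of the nephron lists, 160 genes higher in array 2 remained. These are not free of tubular genes by any check. Outside the lists, 9 Cyp and 15 Slc genes were 2-fold or more higher and stayed in the count. The share of 2-fold genes that were higher in array 2 was 93.9%, and 61.9% without a filter, where dim probes enter. Spike-in scaling gave medians of -0.087 for Treg core, 0.0065 for tissue Treg, -0.0001 for type 2, -0.25 for cell cycle, -0.24 for interferon gamma and 0.95 for proximal tubule genes. No scaling gave -0.062, 0.032, -0.22 and -0.21 for Treg core, tissue Treg, cell cycle and interferon gamma. Normexp gave -0.15 for interferon gamma and 0.86 for proximal tubule genes, and the cause was not tested. With the value table's columns taken by their labels, signs turned, since each column holds the values that the scanner output records under the other lot: 13 genes were higher in lot M and 184 in lot I. Its list medians were 0.030 for Treg core, -0.064 for tissue Treg, 0.060 for suppressive, -0.057 for type 2, 0.089 for type 1, -0.13 for follicular, 0.053 for chemokine receptor, 0.19 for cell cycle, -0.17 for heat shock, 0.068 for type I interferon, 0.18 for interferon gamma, -0.071 for glycolysis, -0.067 for oxidative phosphorylation, 0.11 for cholesterol, -0.28 for macrophage, -0.28 for neutrophil, -1.01 for proximal tubule, -0.44 for distal nephron and -0.51 for red cell genes. Single genes in it were Hrc at -2.16, B3galnt1 at -2.15, Fgb at -2.09, Lama1 at -1.93, Gorasp1 at -1.85, Mlana at -1.83, Pdk4 at -1.66, Tmem82 at -1.62, Steap1 at -1.63, Elovl2 at -1.61, Ren2 at 2.30, E2f4 at 1.76, Frs3 at 1.56, Syce1 at 1.12, Tmem51os1 at 1.08 and Hand2 at 1.03. No paired analysis was possible because each lot has 1 array and no test was run. Signal over background limits the dim genes, whose differences spread by 0.366 at log2 signals from 4 to 6 and by 0.079 above 12.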

Other observations

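The families and genes in this part were looked at after the main results were seen, and the list of glucocorticoid-induced genes was fixed before its own values were seen.

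Genes outside the lists were grouped into families by the start of their symbols. Families were kept if they had at least 10 measured genes, with at least 8 of them outside the lists. Of the 143 such families, 13 lay above the central 95% of random lists and 6 below. By chance 7.15 of 143 would fall outside if genes varied independently. The cytochrome P450 genes (Cyp) had a median of 0.45 over 34 genes, 9 of them 2-fold or more higher in array 2, including Cyp2d26 (1.25) and Cyp2a4 (1.23). Claudins, proteins of epithelial tight junctions, had a median of 0.29, with Cldn10 at 0.62 and Cldn2 at 0.58, and kallikreins had a median of 0.28 with 10 of 15 higher and Klk1 at 0.55. Collagen genes had a median of 0.44 with 8 of 13 higher and 5 lower, the lowest at -0.65, and the basement membrane genes Col4a2 at 0.80 and Col4a4 at 0.62. Aldehyde dehydrogenases had a median of 0.27. The other families above the central 95% were Car (0.28), Tspan (0.18), Myo (0.13), Klf (0.12), Nudt (0.076), Atp (0.066), Slc (0.055) and Mrpl (0.053), the last 2 with medians smaller than the 0.06 by which spike-in scaling shifts every gene. Below the central 95% were the zinc finger genes (Zfp), with a median of -0.034 over 322 genes, lower than all 10000 random lists, and the Ccdc (-0.033), Phf (-0.068) and Taf (-0.073) families. Centrosomal genes (Cep) had a median of -0.09 with 26 of 37 lower, including Cep55 (-0.41), and interferon-inducible genes (Ifi) a median of -0.10 with 5 higher and 6 lower.

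Several genes that glucocorticoids induce were higher in array 2. Fkbp5, a co-chaperone of the glucocorticoid receptor, differed by 0.91 ± 0.14, Klf9 by 0.94 ± 0.21, Tsc22d3, which encodes the leucine zipper protein GILZ, by 0.72 ± 0.14, and Per1 by 0.37 ± 0.20. Il7r, the interleukin 7 receptor, differed by 0.50. Zbtb16, another gene that glucocorticoids induce, went the other way at -0.34 ± 0.27. More glucocorticoid action on the cells of array 2 may account for this, and it was tested on a further list of 20 glucocorticoid-induced genes. That list had a median of 0.1497, above 9998 of 10000 random lists, with 15 of 19 measured genes higher, including Ddit4 (0.56), Errfi1 (0.53) and Txnip (0.49), and 4 lower, including Anxa1 (-0.25). The median fell just short of the 0.15 set in advance, so the question stays open. The list could not separate such action on Tregs from tubular RNA, since the source of each transcript was not determined. Tubular RNA stays open as a source of genes such as Mt1 (0.37) and Sgk1 (0.26), which kidney tubules also express. It was not checked as a source of Fkbp5, Klf9, Tsc22d3 and Per1.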
